A study of Mus musculus with 11 samples.

How the data were processed

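RNA from mouse tissue labelled as liver and tumor was hybridised to 2-colour microarrays, 1 array for each of 11 mice. Per the labels, the Cy5 channel held the RNA of the mouse and the Cy3 channel held a commercial mouse universal reference, a pool of RNA used as a common denominator, so the reference is no sample of either group. The genotype labels give 2 groups: 4 mice with a tamoxifen-inducible Cre and floxed Pten (here Pten mice) and 7 mice with the same Cre and floxed Vhl and Pten (here Vhl/Pten mice). All had been given tamoxifen, which activates the Cre and deletes the floxed genes. Neither a mouse without deletion nor a mouse with Vhl deletion alone was analysed here, and the labels do not say which share of each specimen was tumor. Replicates were numbered within each genotype in accession order, so these numbers only name the arrays.

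The values used were the deposited table of 45220 probes on 11 arrays, taken as log2 ratios. The log base, the formula, the background correction and the normalization are not given in the sources used here. The base was taken as 2 because of the range of the values, and each array's median lay between 0.016 and 0.045. The direction, mouse over reference, is likely rather than stated: 28 of 28 measured hepatocyte markers had ratios above 0 on every array, with medians from 5.12 to 6.98. No scanner files were used, so nothing is known here of background or saturation on single spots, and the number of arrays limits the precision. The table had 0 missing values. It held exact zeros, among them 823 unnamed probes at 0 on every array, which look like placeholders; they were kept as values in the main test.

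Genes were named from the platform annotation, which listed 33026 probes with 1 gene symbol and 0 with several, and did not list 12194 probes. Of the named probes, 32438 took a current symbol through their gene entry in the mouse RefSeq gene table of assembly GRCm38.p6, 36 through an accession, and 552 kept the platform symbol. No genome was used, so probe positions are not given. Different probes of a gene were averaged, giving 22479 genes; 6140 genes had 2 or more probes, and pairs of probes of a gene correlated across arrays with a median r of 0.578, against -0.017 for probes of different genes. These correlations describe probes, which are not independent replicates.

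The difference Vhl/Pten minus Pten was tested per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all 22479 genes and a threshold of 0.05. A gene needed values on at least 3 Pten and 5 Vhl/Pten arrays, which all genes had. Errors beside the differences of genes are the standard errors of that fit, and errors beside group means are SDs. For the gap between 2 lists of cell markers, errors are over mice (pooled variance of the lists' difference per array) or over genes, which treats list members as independent. For the gap between hepatocyte and pericentral medians they come from 2000 bootstrap draws of genes, with the same limit. For 30 gene lists, camera was run with its preset correlation of 0.01, then with a correlation estimated per list, and fry beside it; adjustment was over the 30 lists. Member counts are given over all genes and adjusted over the list alone. For Vhl and for counts of exact zeros, all 330 splits of the arrays into 4 and 7 were enumerated in a two-sided exact permutation test. The smallest p that this test can give is 0.00303.

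The permutation test of exact zeros and the gaps between lists were chosen after seeing the data. The groups, the other tests described above, the lists and the rule for named genes were fixed in advance. That rule took 15 preset genes, of which Pten and Ddx3y were not measured, the 10 largest differences on each side among genes past the threshold (leaving out clone-type symbols), and up to 3 members of each list with the largest difference past the threshold. It gave 117 measured genes. Other genes named below are list members given as examples, chosen after their values were seen.

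Other settings fixed before the data were examined were centring on array medians, quantile normalization, other filters on missing values, the most variable probe per gene, a test per probe, leaving out the less variable genes, a trended and robust prior, array weights, the number that ends the source name of the mouse channel as a replicate block, a covariate made of Xist and 3 Y-linked genes, other thresholds, and leaving out each array. Exact zeros as missing, cyclic loess, scale normalization and an exact permutation test of each list's median per array were chosen after seeing the data. A result past the threshold in neither the main nor the alternative setting was counted as keeping its side. The covariate is a property of mice and was used only as a check.

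The test was checked on simulated values for 22479 genes with the real arrays' spread, 200 of them changed by known amounts. It called 6% of genes changed by 0.5 on the log2 scale, 46% at 1, 88% at 2 and 96% at 3, with 6 false calls among 22279 unchanged genes. With so few genes changed, the adjustment was stricter than on the real arrays, where 10272 genes passed. These rates therefore do not give the share of changes found on the real arrays. With no simulated change the test called 0 genes and 0 lists. Genes were simulated independently, whereas the estimated correlations between members were 0.614 for the hepatocyte and 0.693 for the pericentral list. The 0 lists therefore do not give the rate of false list calls on the real arrays. Multiplying the ratios of 1 group by 0.8 gave a hepatocyte list median of -1.25, which cyclic loess brought to 0.0015. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.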

Results

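Expression was measured in liver and tumor tissue from 11 mice, each on its own 2-colour array against a common reference RNA. All mice carried a tamoxifen-inducible Cre recombinase. In 4 mice (Pten mice) it acted on floxed Pten, which encodes a phosphatase that opposes PI3-kinase signalling. In 7 mice (Vhl/Pten mice) it acted on Pten and on Vhl, which encodes the ubiquitin ligase component that marks hypoxia-inducible factor (HIF) for degradation. The series title poses the question of whether Vhl status alters liver cancers that arise after Pten loss, and the labels allow a single comparison, Vhl/Pten against Pten. Values are log2 ratios of mouse tissue over reference, a direction that is likely but not stated.

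Vhl itself was lower in Vhl/Pten mice, at -0.90 ± 0.20 (SD, n = 7) against -0.04 ± 0.26 (SD, n = 4), a difference of -0.85 (SE 0.15, adjusted p = 0.000736). All 7 Vhl/Pten arrays lay below all 4 Pten arrays (exact permutation p = 0.00303, the smallest the 330 splits can give). Vhl was read by 1 probe whose position relative to the deleted part is not known, so it is only a limited check on the labels. The check is limited further because 45.7% of all 22479 genes differed between the genotypes. No probe was listed for Pten, and deletion of that gene was not checked here.

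Several classical HIF targets rose in Vhl/Pten mice, and all 7 arrays exceeded all 4 Pten arrays for each of the 5 genes that follow. Car9, a membrane carbonic anhydrase, rose by 1.49 (SE 0.11, adjusted p = 8.68e-07). Vegfa, the angiogenic growth factor, rose by 1.31 (SE 0.19), and Slc2a1, the GLUT1 glucose transporter, by 1.29 (SE 0.23). Mxi1, a MYC antagonist, rose by 2.05 (SE 0.32), and Hmox1, which degrades heme, by 1.77 (SE 0.24). Other targets did not follow: Pdk1, Kdm3a, Hilpda and Higd1a fell, by 0.75, 0.68, 0.67 and 0.62. Epo, the erythropoietin gene, differed by 0.71 (SE 0.35, adjusted p = 0.118), and Plin2, a lipid droplet coat gene, by 0.06 (SE 0.25, adjusted p = 0.864). Of 30 measured HIF targets, 11 were higher, 4 lower and 15 did not pass the test (12 higher and 4 lower when adjusted over the list alone). Among all 22479 genes, 5009 were higher and 5263 lower. The HIF list as a whole had a median difference of 0.11 and did not stand apart from other genes (camera adjusted p = 0.246).

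Most measured genes of the glycolysis list were higher in Vhl/Pten mice. Pklr, the liver pyruvate kinase, stood in the lipid synthesis list instead and fell by 2.28 (SE 0.12). Pfkl, the liver phosphofructokinase, rose by 3.10 (SE 0.17), Hk1, a hexokinase, by 2.22 (SE 0.23) and Gapdh by 1.79 (SE 0.20), each with 7 of 7 arrays above all Pten arrays. The probes of a gene disagreed in size here: the 7 Gapdh probes ran from -0.33 to 3.24 and the 2 Hk1 probes from 1.01 to 3.42. Tpi1 and Pkm rose by 1.79 and 1.25, while Hk2 and Pgam1 fell by 0.61 and 0.59. In all, 9 of 15 measured members rose, 2 fell and 4 did not pass the test (9 and 2 adjusted over the list alone), with a median difference of 0.89 (camera adjusted p = 0.00516; adjusted p = 0.865 with an estimated correlation).

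The largest median shift of the 30 lists was in a list of Wnt targets named for the hepatocytes around the central vein. Which cells of the liver and tumor tissue held these transcripts was not measured. With no undeleted mouse analysed, a rise in Pten mice cannot be told from a fall in Vhl/Pten mice. Lgr5, a receptor for R-spondins, which enhance Wnt signalling, fell by 4.24 (SE 0.88, adjusted p = 0.00202) from 7.25 ± 0.14 (SD, n = 4) to 3.01 ± 1.93 (SD, n = 7). Nkd1 and Sp5, both induced by Wnt signalling, fell by 4.06 (SE 0.63) and 3.99 (SE 0.82), and Glul, the glutamine synthetase of pericentral hepatocytes, by 3.51 (SE 0.67, adjusted p = 0.00114). All 7 Vhl/Pten arrays were below all Pten arrays for these 4 genes. Axin2, the Wnt feedback gene, fell by 3.83. Oat, ornithine aminotransferase, fell by 2.80 (adjusted p = 0.0388), and its call was lost without any of the 4 Pten arrays or without Vhl/Pten replicate 7, with adjusted p up to 0.0848, under quantile normalization (adjusted p = 0.0865) and with the Xist and Y-linked covariate (adjusted p = 0.0540). Of 15 measured targets, 13 fell, 0 rose, and Znrf3 (-0.63) and Notum (0.11) did not pass the test (14 lower adjusted over the list alone). The median difference was -2.26 (camera adjusted p = 0.000136; adjusted p = 0.865 with an estimated correlation), and -2.32 after cyclic loess, a scaling chosen after seeing the data. The fall was deeper on 2 Vhl/Pten arrays: the list's median was 0.869 on replicate 6 and 0.902 on replicate 7, against 2.76 to 3.80 on the other 5 Vhl/Pten arrays and 4.71 to 5.74 on Pten arrays.

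**Figure D1:**
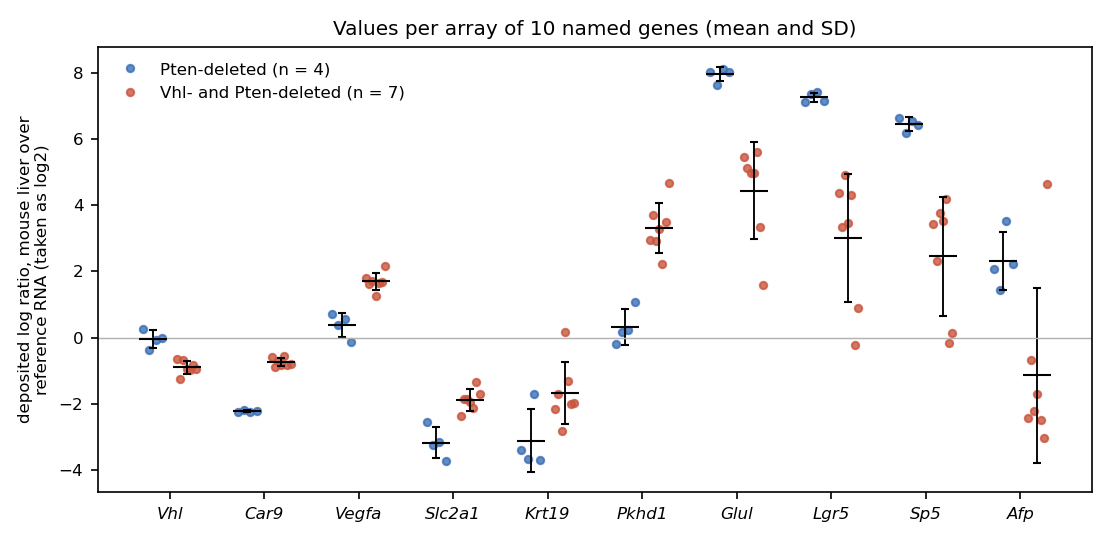
Deposited log ratios (vertical axis, log2 of mouse tissue over reference) of 10 named genes on each of 4 Pten arrays (blue) and 7 Vhl/Pten arrays (red); black lines give the mean and SD. Car9, Vegfa and Slc2a1 are higher and Vhl, Glul, Lgr5 and Sp5 lower on all 7 Vhl/Pten arrays, while Afp has 1 Vhl/Pten array, at 4.63, above all others.

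Genes of the differentiated hepatocyte were lower in Vhl/Pten mice in the values as deposited. Alb, the albumin gene, fell by 1.42 (SE 0.11, adjusted p = 1.59e-06), Hpd and Tdo2, which break down tyrosine and tryptophan, by 1.91 (SE 0.22) and 1.90 (SE 0.14), and Trf, transferrin, by 1.51 (SE 0.13), each on 7 of 7 arrays. Of 28 measured markers, 23 fell, 1 rose (Cebpa, by 0.55) and 4 did not pass the test (25 lower and 1 higher adjusted over the list alone). The median difference was -1.11 (camera adjusted p = 5.62e-09; adjusted p = 0.865 with an estimated correlation), at percentile 9.99 of 10000 random lists matched on mean ratio. The matched genes share the markers' high ratios and may include other hepatocyte genes. That percentile therefore cannot tell a loss of hepatocyte expression from a shift of high ratios. Genes with high ratios were lower as a class: the median difference was -0.96 over the 207 genes with a mean ratio of 5 to 6 and -0.91 over the 186 above 6, against -0.06 for ratios of 0 to 1. After cyclic loess, which removes this trend, the hepatocyte list had a median of -0.07 (camera adjusted p = 0.571) with 11 genes lower and 5 higher, and Alb, Hpd, Tdo2 and Trf were at -0.68, -1.15, -1.02 and -0.57; Trf lost its call under scale normalization (-1.55, adjusted p = 0.0555). Quantile normalization gave a list median of -0.27 (adjusted p = 0.170).

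**Figure D2:**
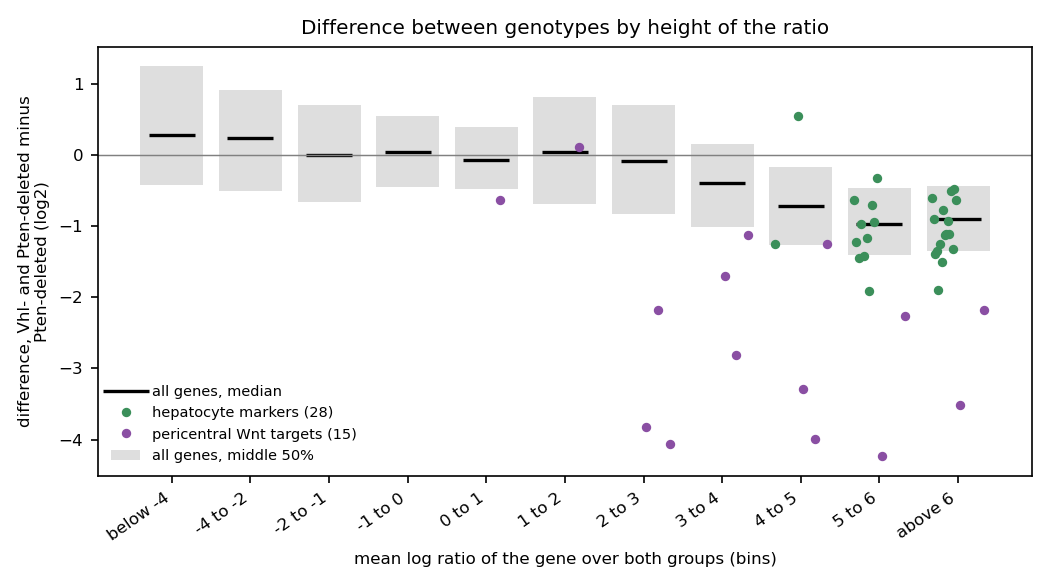
Difference between genotypes (vertical axis, log2, Vhl/Pten minus Pten) for genes grouped by their mean log ratio over both groups (horizontal axis, bins); grey boxes span the central 50% of all genes, black lines are medians, and points are 28 hepatocyte markers (green) and 15 pericentral Wnt targets (purple). The median of all genes falls to -0.96 in the bin of 5 to 6, and most Wnt targets lie below the median of their own bin.

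The calls of 4 metabolic lists also depended on the scaling. Lipid storage and uptake genes had 12 of 19 members lower and 2 higher (13 and 3 adjusted over the list alone; median -1.14, camera adjusted p = 0.00951; adjusted p = 0.865 with an estimated correlation). In that list Vldlr, a lipoprotein receptor, fell by 4.09 (SE 0.59), Fabp4, a fatty acid carrier, by 2.77 (SE 0.76) and Cidec, a lipid droplet fusion gene, by 2.41 (SE 0.45), all on 7 of 7 arrays; under quantile normalization Fabp4 was at -2.01 (adjusted p = 0.0755). Bile acid genes had 10 of 19 lower and 0 higher (10 and 0 adjusted over the list alone; median -0.82, camera adjusted p = 0.00516; adjusted p = 0.865 with an estimated correlation), with the transporter Abcc4 down by 3.76 (SE 0.57). Cytochrome P450 and drug metabolism genes had 14 of 24 lower and 2 higher (15 and 4 adjusted over the list alone; median -1.02, camera adjusted p = 0.00516; adjusted p = 0.865 with an estimated correlation), with Cyp2e1 down by 2.18 (SE 0.42) and Cyp2c29 by 2.07 (SE 0.18), or by 1.25 and 1.08 after cyclic loess. Urea cycle and amino acid genes had 13 of 23 lower and 4 higher (13 and 4 adjusted over the list alone; median -0.71, camera adjusted p = 0.0187; adjusted p = 0.935 with an estimated correlation). The higher ones included Ass1 and Asl, consecutive enzymes of the urea cycle, at 1.99 and 2.22, and Hal, histidine ammonia-lyase, at 2.64 (SE 0.85), whose call was lost without Pten replicate 2 (2.02, adjusted p = 0.0860) or Pten replicate 3 (1.84, adjusted p = 0.0833). After cyclic loess the medians of these 4 lists were -0.79, -0.15, -0.18 and 0.11, and the camera adjusted p were 0.253, 0.537, 0.801 and 0.822. The lipid storage list then still had 10 genes lower and 1 higher. Bile acid genes had 7 lower and 3 higher, P450 genes 6 and 4, and urea cycle genes 7 and 5. The urea cycle list also turned to 0.23 under quantile normalization.

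Several genes of the extracellular matrix and stellate cell list were higher in Vhl/Pten mice. Des, desmin, rose by 4.17 (SE 0.22), Tgfb1 by 3.86 (SE 0.29) and Loxl1, which crosslinks elastin, by 2.58 (SE 0.36), each on 7 of 7 arrays. Mmp2 and Dcn rose by 1.84 and 1.78, whereas Col1a1 (-0.30), Vim (-1.31) and Lum (-0.10) did not pass the test. Neither did the list members Lrat (0.75), Reln (0.12), Pdgfra (0.36) and Pdgfrb (0.73). Of 24 measured genes 10 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.72 (camera adjusted p = 0.00820; adjusted p = 0.935 with an estimated correlation), and the call was lost with the less variable genes left out (adjusted p = 0.0868). Endothelial markers did not pass as a list: 11 of 23 were lower and 3 higher (12 and 3 adjusted over the list alone; median -0.67, camera adjusted p = 0.0625), and the median lay at percentile 12.9 of 10000 random lists matched on mean ratio. Flt1 fell by 1.85 (SE 0.42) and Emcn by 1.90 (SE 0.47), on 6 of 7 arrays each, while Eng rose by 2.30 (SE 0.22); Emcn did not pass under quantile normalization (-1.37, adjusted p = 0.0538). The endothelial list passed without Vhl/Pten replicate 2 (adjusted p = 0.0329) or replicate 7 (adjusted p = 0.0296).

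Biliary and oncofetal genes moved in both directions. Pkhd1, a gene of bile duct cilia, rose by 2.997 (SE 0.39) and Cftr, the chloride channel of bile ducts, by 1.97 (SE 0.45). Krt7 was higher by 2.21 (SE 0.75, adjusted p = 0.0305), but by 1.46 (adjusted p = 0.102) without Pten replicate 3, and its call was also lost without Vhl/Pten replicate 2 (adjusted p = 0.0536) or 5 (adjusted p = 0.0543). Krt19 was higher by 1.43 (SE 0.53, adjusted p = 0.0449), a call lost without any of Pten replicates 1, 2 or 4 or Vhl/Pten replicates 1, 2, 5, 6 or 7 (adjusted p up to 0.120), after quantile normalization (adjusted p = 0.0706) or cyclic loess (adjusted p = 0.0583), and with the Xist and Y-linked covariate (adjusted p = 0.0687). Sox9 and Epcam, ductal and progenitor genes, differed by 0.35 (SE 0.88, adjusted p = 0.779) and 0.25 (SE 0.52, adjusted p = 0.725). Of 26 biliary markers 6 were higher and 2 lower (3 and 1 adjusted over the list alone; median 0.09, camera adjusted p = 0.583). Afp, the fetal serum protein, was lower by 3.45 (SE 1.23, adjusted p = 0.0382), at -1.13 ± 2.64 (SD, n = 7) against 2.32 ± 0.87 (SD, n = 4). The Afp call was lost under scale normalization (adjusted p = 0.0783) and on leaving out any array except Vhl/Pten replicate 7 (adjusted p up to 0.103). Without Vhl/Pten replicate 7 the Afp difference was -4.41 (adjusted p = 4.18e-05). Hmga2, a chromatin protein of fetal tissue, rose by 2.06 (SE 0.16). Of 18 oncofetal genes 3 rose and 4 fell (3 and 4 adjusted over the list alone), and the list's median of 0.04, its mean of -0.36 and its camera direction, up, differed in sign (adjusted p = 0.986). Those that fell include Trf, which the hepatocyte list also holds.

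Lipid synthesis genes did not pass the test as a list, although single members changed. Dgat1, which makes triglyceride, rose by 2.71 (SE 0.14) and Fads1, a fatty acid desaturase, by 2.38 (SE 0.37), while Pklr, the liver pyruvate kinase, fell by 2.28 (SE 0.12), or by 1.49 under quantile normalization. Fasn, fatty acid synthase, was at 3.53 ± 0.68 (SD, n = 7) against 3.61 ± 0.38 (SD, n = 4), a difference of -0.09 (SE 0.34, adjusted p = 0.861). Of 21 members 6 rose and 6 fell (6 and 7 adjusted over the list alone), with a median of -0.13, a mean of 0.03 and a camera direction of down (adjusted p = 0.951). Fatty acid oxidation genes had 9 of 21 lower and 1 higher (9 and 1 adjusted over the list alone; median -0.47, camera adjusted p = 0.0905), and the median was 0.05 after cyclic loess; the list passed without Pten replicate 1 (adjusted p = 0.0496) or Vhl/Pten replicate 1 (adjusted p = 0.0485). In it Pdk4, which inhibits pyruvate dehydrogenase, fell by 4.53 (SE 0.44), Acot1 by 4.46 (SE 0.70) and Cyp4a14 by 3.82 (SE 1.09), all on 7 of 7 arrays. Mitochondrial oxidative phosphorylation genes had 9 of 26 lower and 4 higher (9 and 4 adjusted over the list alone; median -0.29, camera adjusted p = 0.166), with Ndufa4 down by 2.13 (SE 0.17) and Cs, citrate synthase, by 1.84 (SE 0.18); after cyclic loess this list passed (adjusted p = 0.0398, median -0.45).

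Proliferation genes were split. Mcm3 and Tk1, used in DNA replication, rose by 1.58 (SE 0.18) and 1.52 (SE 0.25), whereas Bub1, a mitotic checkpoint kinase, fell by 2.74 (SE 0.20), with 1 of its Pten spots at exactly 0. Of 29 members 9 rose and 6 fell (9 and 6 adjusted over the list alone; median 0.01, camera adjusted p = 0.676). Among targets of FoxO, Sesn3 and Ccng2 fell by 2.20 (SE 0.22) and 2.12 (SE 0.35) and Txnip rose by 2.03 (SE 0.34). In that list 5 of 18 rose and 4 fell (5 and 4 adjusted over the list alone), with a median of 0.08, a mean of -0.07 and a camera direction of up (adjusted p = 0.951). Gluconeogenesis and glycogen genes had 1 of 10 higher and 2 lower (0 and 2 adjusted over the list alone; camera adjusted p = 0.583); their median of -0.18 became 0.20 after cyclic loess. Gbe1, the glycogen branching enzyme, fell by 1.71 (SE 0.18).

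Across all 22479 genes, 10272 differed between the genotypes (45.7%), 5009 higher and 5263 lower in Vhl/Pten mice, with a median difference of -0.03 and an SD over genes of 0.986. The largest increases included Lrrc24 (5.16, SE 0.82), Syt10 (4.88, SE 0.18), Igfbp2, an insulin-like growth factor binding protein (4.48, SE 1.12), Rn28s1, a ribosomal RNA (4.32, SE 0.12), and the kinase gene Pim3 (4.30, SE 0.27). The largest decreases included Dner (-7.51, SE 0.89), Acsm4 (-7.31, SE 0.88), Tbx4 (-6.93, SE 1.09), Prokr2 (-6.50, SE 0.97) and Trim12a (-5.96, SE 0.23), the last from a multigene family whose probes may share transcripts. Arrays correlated at r of 0.850 to 0.912 within Pten mice, 0.847 to 0.946 within Vhl/Pten mice and 0.684 to 0.775 between them, over probes, which are not independent replicates. Named probes at exactly 0 numbered 183 to 319 on Pten arrays and 8 to 44 on Vhl/Pten arrays (exact permutation p = 0.00303). The sample titles also part by genotype: the mouse numbers of the groups do not overlap, and the titles are written in different forms. What this difference stands for is not stated. The labels give no array batch, so a batch that followed genotype cannot be separated from it. That limit covers each gene above, including Rn28s1, which was at 5.77 ± 0.13 (SD, n = 7) against 1.45 ± 0.13 (SD, n = 4).

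**Figure D3:**
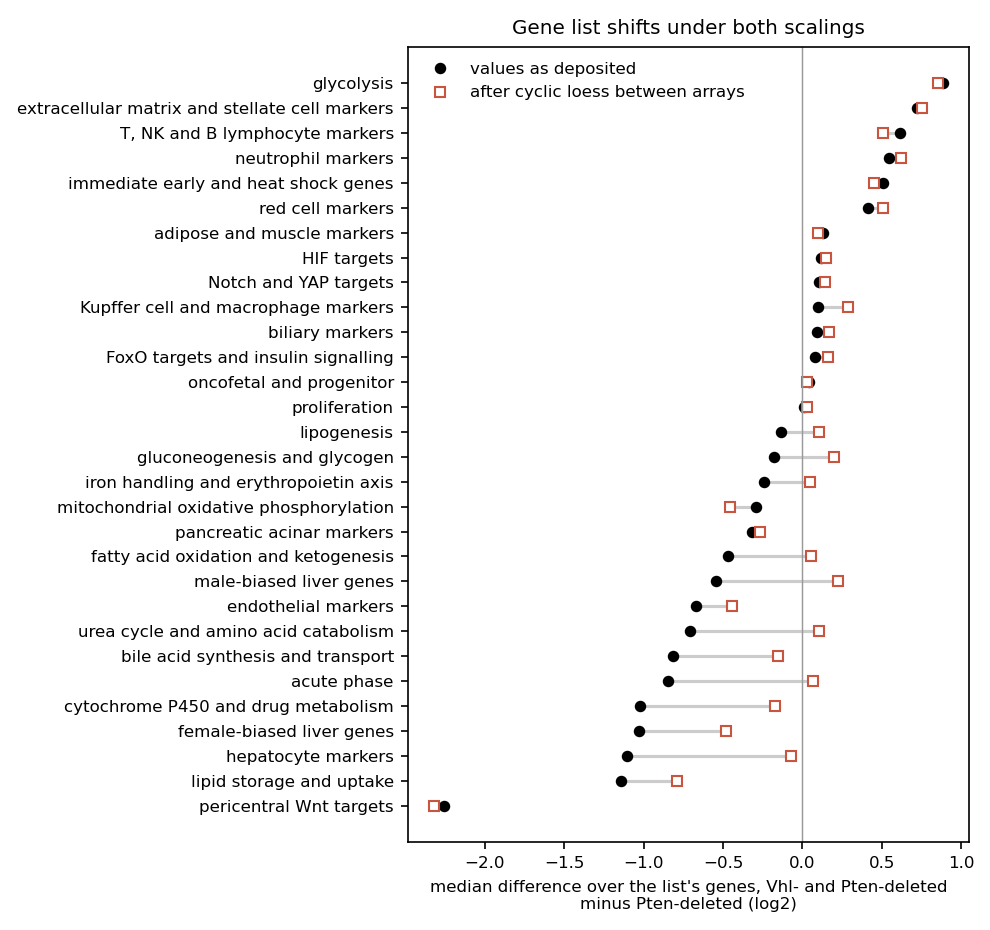
Median difference of each of 30 gene lists (horizontal axis, log2, Vhl/Pten minus Pten) as deposited (filled circles) and after cyclic loess between arrays (open squares). The pericentral Wnt list stays near -2.3 in both, at -2.26 and -2.32, while the hepatocyte list moves from -1.11 to -0.07.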

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

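In 294 tests of a genotype's arrays for a sample far from the rest, 27 named genes or list medians stood out, against about 1 in 20 expected by chance.

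Among Vhl/Pten arrays, replicate 7 had Afp at 4.63 while the nearest of the others was at -0.68, Mxi1 at -0.70, Cs at -1.07 and a median of -1.71 over adipose and muscle markers. Replicate 6 had Igfbp2 at -1.07, Tbx4 at -1.66, Hal at 3.77, Timd4, a resident macrophage marker, at 1.66 and Zap70, a T cell kinase gene, at -0.40. Replicate 2 had Mmp9, a protease of neutrophils, at 0.57 with the nearest other array at -1.88, and a median of 3.67 over neutrophil markers with the nearest at 1.95.

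Among Pten arrays, replicate 2 had Dner at 0.22 with the nearest other array at 5.58, Prokr2 at 2.20, Myot at 4.74, Nkd1 at 2.25, Zap70 at 1.75 and a pericentral Wnt list median of 4.71 with the nearest at 5.57. Replicate 3 had Krt19 at -1.70, Krt7 at -4.50, Cyp2c29 at 8.02 and Myh4 at -1.21, where 2 of the other Pten values were exactly 0. Replicate 1 had Mcm3 at -2.30, Vldlr at 0.70, Actn3 at -2.52, Prom1 at 3.93 and Xist, the X-inactivation transcript, at -4.20. The mean of the Y-linked genes was 1.95 on replicate 1, against -3.29 to -2.42 on the other Pten arrays. Low Xist with high Y-linked genes is the pattern of a male mouse. Replicate 4 had Abcc4 at 1.34.

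Probes without a gene name in the annotation used here also differed: 4377 of 11371 passed the threshold (38.5%), 2041 higher and 2336 lower in Vhl/Pten mice.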

How the results depend on the processing

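Cyclic loess, scale normalization, exact zeros as missing and the exact permutation of list medians were chosen after seeing the data. Of 111 named genes past the threshold, 90 kept their direction and call in all of the 25 settings that tested them. With each array left out, genes differing ranged from 9176 to 10327, higher from 4466 to 5042 and lower from 4710 to 5285. Quantile normalization called 10083 genes, 9623 of them shared in direction with the main result, cyclic loess 10342 (9521 shared) and the Xist and Y-linked covariate 10114 (9803 shared). Testing per probe gave 15673 calls (7557 higher, 8116 lower), counting probes. Leaving out the less variable genes gave 6728, with 3236 lower, since fewer genes were tested. Requiring a log2 difference of at least 1 gave 5178 (2798 higher, 2380 lower). For the other changes the cause was not tested.

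Quantile normalization ended the calls of the hepatocyte and lipid storage lists (adjusted p = 0.170 for each), bile acid (0.531) and P450 (0.889) lists and turned the urea cycle list upward (0.912). Cyclic loess gave adjusted p = 0.571 for hepatocyte, 0.253 for lipid storage, 0.537 for bile acid, 0.801 for P450 and 0.822 for urea cycle lists. Scale normalization gave 0.0718 for bile acid, 0.0806 for P450 and 0.325 for urea cycle lists. Without the less variable genes, bile acid, urea cycle and matrix lists had 0.0881, 0.0650 and 0.0868. Camera with an estimated correlation ended all 8 list calls, at adjusted p of 0.865 (glycolysis, hepatocyte, lipid storage, bile acid, P450, pericentral) or 0.935 (urea cycle, matrix). The exact permutation of list medians left bile acid at 0.164 and urea cycle at 0.0568. Fry, which asks whether members move 1 way on balance, also called HIF targets (0.0202), iron (0.00560), endothelial (0.0247), lymphocyte (0.00356), acute phase (0.00955) and immediate early lists (0.00203). Testing per probe also called fatty acid oxidation, acute phase and immediate early lists (0.0398 each), endothelial (0.000641), and lymphocyte and neutrophil lists (0.00387 each). None of the 8 list calls ended on leaving out any 1 array. Gys2, a glycogen synthase gene at -0.70 in the main test, was at 0.25 after quantile normalization and 0.19 after cyclic loess.

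The number that ends the source name of the mouse channel did not pair the arrays: r of deviations from group means was -0.148 to 0.104 over 7 pairs with equal numbers and -0.138 to 0.198 over 21 with different ones. With it as a replicate block, 9398 genes differed (4629 higher, 4769 lower), and Krt19 (adjusted p = 0.0734), Oat (0.0651), Zap70 (0.0853), Sult2a1 (0.0629) and Prom1 (0.0850) did not pass. No signal over background was known, so spots near background could not be marked.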

Other observations

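Tests chosen only after the result was seen were those of receptor genes, cyclic loess, scale normalization, exact zeros, hepatocyte share and the permutation of list medians. Markers of blood and immune cells moved unevenly. Mzb1 and Pou2af1, genes of antibody-secreting and B cells, rose by 2.35 (SE 0.11) and 2.03 (SE 0.18); of 20 lymphocyte markers 6 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.61, camera adjusted p = 0.0891), and the list passed without Pten replicate 4 (adjusted p = 0.00940). Zap70 was higher by 1.81 (SE 0.68, adjusted p = 0.0462), with adjusted p up to 0.104 on leaving out any array except Pten replicate 2 or Vhl/Pten replicate 6; it also did not pass after cyclic loess (0.0648), scale normalization (0.0723) or with the Xist and Y-linked covariate (0.0688). Mmp9 and Cxcr2, genes of neutrophils, rose by 2.90 (SE 0.48) and 1.21 (SE 0.32), and 2 of 15 neutrophil markers rose and 0 fell (2 and 0 adjusted over the list alone; median 0.54, camera adjusted p = 0.383). Among 22 macrophage markers 4 rose and 4 fell (4 and 3 adjusted over the list alone), Cd68 by 1.39 (SE 0.42) upward and C1qb at -1.54, or -0.85 (adjusted p = 0.0823) under quantile normalization; the median of 0.10 and mean of 0.20 opposed the camera direction, down (adjusted p = 0.986). Of 14 red cell markers 4 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.662). Rhd was at 1.85 (SE 0.42). Alas2, of heme synthesis, was at -1.73 (SE 0.13), or -0.85 under quantile normalization and -1.04 after cyclic loess.

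Immediate early genes Junb and Ier2 rose by 3.94 (SE 0.25) and 3.91 (SE 0.27) on 7 of 7 arrays, while Hspb1, a small heat shock protein gene, fell by 2.43 (SE 0.38). Of 17 such genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.51, camera adjusted p = 0.0625), and the list passed without Pten replicate 2 (adjusted p = 0.0439) or Vhl/Pten replicate 1 (adjusted p = 0.0467) or 5 (adjusted p = 0.0498). Acute phase genes had 8 of 17 lower and 3 higher (9 and 3 adjusted over the list alone; median -0.85, or 0.07 after cyclic loess; camera adjusted p = 0.156), with Orm2 at -1.70 (SE 0.17), or -0.69 after cyclic loess. Notch and YAP genes had 7 of 19 higher and 6 lower (7 and 6 adjusted over the list alone; median 0.10, camera adjusted p = 0.662), Ankrd1 up by 2.41 (SE 0.22) and Wwtr1, the TAZ gene, down by 2.44. Iron genes had 1 of 17 higher and 2 lower (1 and 2 adjusted over the list alone; median -0.25, 0.05 after cyclic loess; camera adjusted p = 0.383), with Fth1, ferritin heavy chain, at -1.42 (SE 0.21). Acinar markers had 3 of 16 higher and 2 lower (3 and 2 adjusted over the list alone; median -0.32, camera adjusted p = 0.583), and adipose and muscle markers 4 of 12 higher and 2 lower (4 and 2 adjusted over the list alone; median 0.13, camera adjusted p = 0.784). Male-biased liver genes had 1 of 15 higher and 6 lower (1 and 6 adjusted over the list alone; median -0.55, 0.23 after cyclic loess, -1.04 with the Xist and Y-linked covariate; camera adjusted p = 0.163), and female-biased genes 0 of 17 higher and 4 lower (0 and 1 adjusted over the list alone; median -1.03, -0.48 after cyclic loess with 0 genes lower, -0.75 with the covariate; camera adjusted p = 0.163). The score behind that covariate, Y-linked genes minus Xist, was above 0, the pattern of males, on 1 of 4 Pten and 4 of 7 Vhl/Pten arrays.

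The breadth of the difference was unusual: 10272 genes passed, against at most 21 in the other splits drawn (1 of 100 splits as large, the real one). The same held for the 5009 higher (highest other 19) and 5263 lower genes (highest other 2). A chance division of the arrays is thus unlikely, though 1 in 100 was the smallest share possible. These splits do not tell what sets the 2 groups of arrays apart. Of 1359 olfactory and vomeronasal receptor genes, which liver should hardly transcribe, 17.9% passed (60 higher, 183 lower), and differences over 73 ribosomal protein genes had an SD of 0.621 where their standard errors give 0.181, which suggests effects of probes or of an array batch that follow genotype. Exact zeros parted the genotypes without overlap (exact permutation p = 0.00303, the smallest possible), as differing processing could produce. Compression of ratios does not account for the breadth, as 10342 genes passed after cyclic loess. Genotype and an unlabelled batch cannot be told apart here, since no label separates them, so the 10272 genes may include many that do not reflect Vhl.

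For the lower hepatocyte markers, compression of high ratios on Vhl/Pten arrays and real loss of hepatocyte expression cannot be told apart. The list median was -0.0703 after cyclic loess, but these markers lie among the high ratios, so that scaling could remove a real fall as well. A lower share of hepatocytes was taken to raise markers of other cells alike. Matrix genes exceeded endothelial genes by a mean of 1.503 (SE 0.295 over mice, 0.345 over genes taken as independent). This cannot decide against a lower share, since other cell types need not rise alike. After cyclic loess 11 markers still passed as lower, among them Hpd (-1.15), Tdo2 (-1.02), Alb (-0.68) and Trf (-0.57), and 5 as higher.

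Of the 4 explanations tested for the lower pericentral Wnt targets, compression, the sexes of the mice and gene-blind probe effects were argued against. A lower share of hepatocytes was not decided, and an array batch remains confounded with genotype. The median was -2.32 after cyclic loess, -2.28 with the Xist and Y-linked covariate, and 0% of 10000 matched random lists lay as low, which argues against compression, the sexes of the mice and gene-blind probe effects. For a lower share of hepatocytes, matrix genes exceeded endothelial genes by the same 1.503 (SE over mice 0.295), or 1.32 (SE over mice 0.240) after cyclic loess. That contrast cannot decide it, since other cell types need not rise alike. The gap from hepatocyte markers to the list did not decide it, at 1.15 (bootstrap SE over genes 0.595), under 2 standard errors. That error does not measure the spread between mice, and this gap was not tested over mice. Per array, the hepatocyte list median averaged 6.78 ± 0.20 (SD, n = 4) in Pten and 5.57 ± 0.26 (SD, n = 7) in Vhl/Pten mice. The pericentral list median averaged 5.40 ± 0.47 (SD, n = 4) and 2.63 ± 1.23 (SD, n = 7). The gap of 2.25 (SE 0.631) after cyclic loess was computed after the 1.15 was seen, in a scaling that itself raises the hepatocyte list. The hypothesis that Vhl deletion lowers the pericentral Wnt programme in Pten-deleted liver may be tested by staining glutamine synthetase across whole lobules and tumors of both genotypes and by arrays of both run in 1 batch, since sampling of other liver zones, tumor content and batch are untested.

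The count of 8 lists past the threshold is weaker evidence: 52 of 100 splits gave as many (highest other 21), so chance cannot be excluded for that count with the preset correlation. An exact permutation of list medians gave adjusted p = 0.0227 for hepatocyte, lipid storage, P450 and pericentral lists, 0.0303 for matrix and immediate early genes and 0.0390 for glycolysis.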
